A study of Homo sapiens with 12 samples.

How the data were processed

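Stranded total RNA sequencing was carried out on 12 samples of THP-1 cells, an acute myeloid leukaemia line. Per the labels' protocols, cells were transduced with single guide RNAs (sgRNAs), placed under 1 µg/ml puromycin 48 h later and collected at day 4 or day 7, and 100 ng of total RNA went into a stranded total RNA library kit. Groups were taken from the sample titles: SETDB1 sgRNA 9 and non-targeting sgRNA at each day, 3 samples each. The design text names SETDB1 sgRNAs 6 and 9 for the same total of 12 samples, while every SETDB1 title names sgRNA 9, so whether some of these libraries carry sgRNA 6 is not settled, and the groups follow the titles. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The 12 pairs of libraries within groups differed by more than sampling noise (chi-square over its degrees of freedom 1.75 to 15.4, largest p = 9.82e-05), so none was treated as a duplicate.

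The values are whole-number counts per repeat element and strand, as deposited, with a table for each day and 45 elements in both. CASAVA 1.8, BWA and HTSeq are named in the submitters' processing notes, without roles. The genome build, the repeat models, how reads mapping to several places were counted, how the 45 elements were chosen and what the plus and minus columns refer to are not given in the sources used here. If the elements were chosen on these samples, the numbers of higher and of non-overlapping features are not independent of that choice, and 10% is not the chance value for the latter. Repeat copies share sequence, so counts of related models (the L1 models, or THE1C, MSTB1, MSTB2 and MSTC) could be split between them by the counting and are uncertain to that extent. The tables hold neither genomic positions nor rows that name no element, and all 24 count columns were matched to samples by the sample description in their header (0 columns of other samples).

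Each strand of an element was a feature, giving 90 features. edgeR 4.0.16 (in R 4.3.3) filtered them with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 70 features of 39 elements, with both strands of 31 elements. The 20 features left out held 0.121% of the counts, and 5 of them were at 0 in every library. Library sizes were the table totals (27388 to 58916 counts) with TMM factors, since the total depth of the libraries is not given in the sources used here. Fold changes are therefore relative to the other elements of the table, and L1P1_orf2 and L1PA5_3end together take the largest part of its counts, so that a rise in many features can appear as a fall in the rest. All 12 libraries entered one quasi-likelihood fit with 4 groups (8 residual degrees of freedom, biological coefficient of variation 11.4%). The contrasts were SETDB1 sgRNA 9 against non-targeting sgRNA at each day, the difference between these, and day 7 against day 4 in each arm. p-values were adjusted by Benjamini-Hochberg over the 70 features, with a threshold of 0.05. The standard error of a log2 fold change was taken from its F statistic.

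The minus strand share was tested in edgeR with the strands of each library as 2 columns (24 in all), a block for the library and strand by group terms, over 39 elements. Elements higher on both strands were counted among the 31 pairs. Lists of repeat classes fixed beforehand (LTR, ERV1, ERVK, ERVL, ERVL-MaLR, LINE, young L1, SINE, Alu, SVA, DNA, satellite, RNA, and simple repeats) were tested against the other features with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, where at least 3 features were tested. Unlike camera, fry tests a list against no change, so its result depends on the scaling. The ERVK list, whose name patterns matched HERVK and LTR55, and young L1 (L1PA5_3end) had 2 tested features each and were not tested as lists. Those of the ERVK list were both strands of HERVK. The SINE, Alu, SVA, DNA, RNA and simple repeat lists, and the gene lists (interferon response, double-stranded RNA sensing, H3K9 methylation, apoptosis) and cell type markers, had 0 members in the tables. MER34C and MER101B belonged to no list, and the ERV1 list held LTR23-int and LTR26 only, as its name patterns matched no other ERV1 element. Totals of the arms were compared by exact permutation.

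Named features were chosen by a rule fixed before the data were examined. For each day, it took up to 10 features per direction with the largest log2 change among those past the threshold whose 3 SETDB1 libraries all lay above, or all below, the 3 non-targeting ones, plus the most abundant member of each tested list. For the interaction and the time comparisons it took the 5 largest per direction, and in the time comparisons also any feature named above that passed; for the strand share it took the 10 largest per direction. The groups, tests and all alternatives but one were also fixed then.

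The alternatives were DESeq2 size factors, table totals without TMM, no scaling, no count filter, a mean count of at least 50, the DESeq2 1.42.0 Wald test, limma-voom, limma on the log2 strand ratio with pseudocounts of 0.5 and 5, each day fitted alone, a replicate block, camera with an estimated correlation, fry, and leaving out each library in turn. Leaving L1P1_orf2 out of the table was chosen after seeing the data. The scripts were tested on simulated counts drawn from the non-targeting means of the 90 features and the library sizes, 50 datasets for each test. All features had the same dispersion and the strands were drawn independently, so strand shifts shared within a library were absent. In the SETDB1 sgRNA 9 day 4 libraries the minus strand share of all counts ran from 66.2% to 74.6%. The rates below hold for the simulated setting and need not hold for these libraries. For the day 7 comparison, 61% of features changed 1.5-fold, 89.7% of those changed 2-fold and 99% of those changed 4-fold were called, and 5.15% of calls were false. When 30 features were raised 2-fold together, the unchanged ones took a median log2 change of -0.42, and 18.1 of them on average were called lower. For the day 7 strand share, 28%, 59.3% and 89.3% of elements shifted 1.5-fold, 2-fold and 4-fold were called, with 4.12% false calls. For the day 7 lists, a list raised 2-fold was called in 100% of datasets, with 0.54 other lists called on average. The limit given for a count of 0 is 3 counts of the total and covers counting error only. Figures were drawn with matplotlib.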

Results

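Strand-resolved counts of 45 repeat elements were measured in total RNA of THP-1 cells, an established human acute myeloid leukaemia line of monocytic type. The cells carried either SETDB1 sgRNA 9 or a non-targeting sgRNA and were collected at day 4 and day 7, with 3 libraries in each of the 4 groups. SETDB1 is a histone H3 lysine 9 methyltransferase known for silencing repeats, and the series asks whether transposable elements are transcribed in both directions after its depletion. SETDB1 itself is not among the tabulated elements, so its level in each library was not analysed here. The tabulated counts summed to between 27388 and 58916 per library. The totals averaged 50619 ± 7207 with SETDB1 sgRNA 9 and 30587 ± 4110 with the non-targeting sgRNA at day 4 (SD, n = 3), a ratio of 1.65 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). At day 7 they averaged 49914 ± 9993 and 34796 ± 7531 (SD, n = 3), a ratio of 1.43 (two-sided exact permutation p = 0.2). The open reading frame 2 model L1P1_orf2 of the LINE L1 retrotransposon took the most counts, 34.0% ± 1.4 of the non-targeting and 39.2% ± 1.6 of the SETDB1 libraries at day 4 (SD, n = 3). Each strand of an element was treated as a feature, and 70 of the 90 features had enough counts to be tested. All levels below are normalised counts in CPM, scaled to the counts of these 45 elements alone, so a change in a feature is a change relative to the other elements.

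SST1, a satellite repeat, showed the largest rise after 4 days of SETDB1 sgRNA 9. Its plus strand went from 637 ± 124 to 7697 ± 166 CPM (SD, n = 3), 11.9-fold, or 3.58 ± 0.20 on the log2 scale (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.2e-17). ALR, the alpha satellite of centromeres, rose on both strands, by 2.49 ± 0.20 on the minus strand and 1.02 ± 0.21 on the plus strand (log2, SE). HERV3, an endogenous retrovirus, and LTR4, its long terminal repeat, rose on the minus strand, by 0.84 ± 0.15 and 1.13 ± 0.19 (log2, SE). The minus strands of THE1C and MSTB1, long terminal repeats of the mammalian apparent LTR retrotransposons (MaLR), were lower by a log2 change of -0.43 ± 0.12 and -0.47 ± 0.13 (SE).

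In all, 11 of the 70 features were higher and 6 were lower at day 4, and 22 had an unadjusted p under 0.05. The 3 libraries of each arm did not overlap for 18 features, 25.7% against the 10% that chance gives if the elements were not chosen on these samples. LTR60 plus strand (1.17 ± 0.30, adjusted p = 0.00351) and L1PBa_5end plus strand (0.89 ± 0.14, adjusted p = 8.76e-06) completed the features that were higher in every SETDB1 library (log2, SE; edgeR). The other higher features were L1P1_orf2 plus strand (0.39 ± 0.14) and the minus strands of L1PA10_5end (0.40 ± 0.14), L1PA12_5end (0.54 ± 0.17) and L1P1_5end (0.58 ± 0.16). The libraries of the arms overlapped for these 4, which were named after their values were seen. The lower features besides THE1C and MSTB1 were HUERS-P3b on its plus strand (-0.69 ± 0.15) and minus strand (-0.59 ± 0.14), LTR26 minus strand (-0.80 ± 0.22) and MER34C minus strand (-0.94 ± 0.35, adjusted p = 0.0466 in edgeR). L1P1_orf2 minus strand, the most abundant feature of the LINE list, did not pass (0.31 ± 0.13, edgeR adjusted p = 0.075), nor did LTR23-int minus strand (-0.51 ± 0.20, adjusted p = 0.0616) or MLT2B5 minus strand (-0.31 ± 0.22, adjusted p = 0.358). Scaling by table totals gave 8 higher and 9 lower features, and unscaled counts gave 35 higher and 0 lower, with HUERS-P3b, MSTB1, THE1C, LTR23-int and MLT2B5 minus strands then above 0. Without SETDB1 sgRNA 9 day 4 replicate 3 the calls fell from 17 to 10, and LTR26, MER34C, MSTB1 and THE1C minus strands no longer passed; LTR60 was lost without non-targeting day 4 replicate 1, THE1C without non-targeting day 4 replicate 2, and MER34C with DESeq2 and without SETDB1 sgRNA 9 day 4 replicate 1 or non-targeting day 4 replicate 2 or 3.

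By repeat class, the satellites (SST1, ALR, CER and SATR1, 7 tested features) rose as a list at day 4 (camera, preset correlation 0.01, adjusted p = 0.0046; adjusted p = 0.0409 with an estimated correlation). Among them 3 features were higher and 0 were lower (edgeR, also 3 and 0 adjusted over the list alone), with a median log2 change of 0.88. The higher ones were SST1 plus strand and both strands of ALR. CER and SATR1 did not pass, so the calls rest on SST1 and ALR. Strands of an element entered each list as separate members. Of the 10 splits of the day 4 libraries into 3 and 3, 4 called at least as many lists, the real one included. Chance is therefore not excluded for this count of lists. Of 27 LTR features 3 were higher (LTR60, HERV3 and LTR4) and 5 were lower, with 3 and 6 adjusted over the list alone. The LINE list had 5 higher and 0 lower features of 35, with 3 and 0 adjusted over the list alone. The 10 MaLR features held 2 lower (THE1C and MSTB1, both on the minus strand) and 0 higher, also when adjusted over the list alone. LTR23-int and LTR26, the ERV1 list of 3 features, had 1 lower, or 2 adjusted over the list alone, and the ERVL list, HERVL18 and MLT2B5 with 3 features, had 0 calls either way. None of these 5 lists passed camera at day 4, with adjusted p between 0.282 and 0.9. All 5 had a camera direction lower than the other features, which is not a direction against 0: the LINE median (0.07) and mean (0.03), the LTR mean (0.02) and the ERVL median (0.02) lay above 0.

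**Figure D1:**
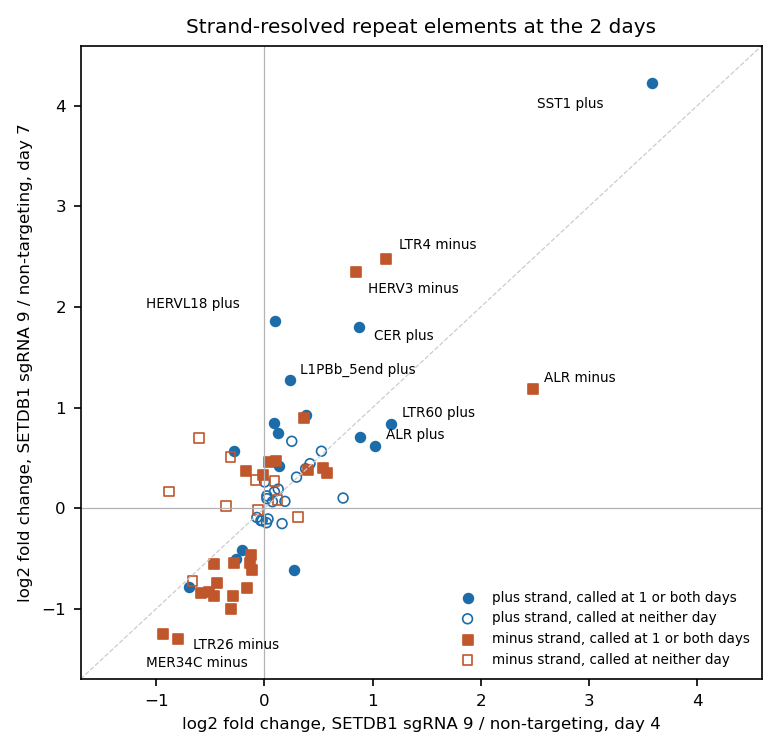
Log2 fold change of SETDB1 sgRNA 9 over non-targeting sgRNA for the 70 tested strand features, day 4 on the horizontal and day 7 on the vertical axis, circles for plus and squares for minus strands, filled where called at either day, with the dashed line marking equal change. SST1 plus strand lies highest at both days (3.58 and 4.23), HERV3 and LTR4 minus strands lie above the line and ALR minus strand (2.49 and 1.19) lies below it.

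At day 7 SST1 plus strand was 18.8-fold higher with SETDB1 sgRNA 9, at 14642 ± 3194 against 779 ± 72 CPM (SD, n = 3; log2 4.23 ± 0.19, SE). LTR4 minus strand rose 5.56-fold (log2 2.48 ± 0.18) and HERV3 minus strand rose 5.09-fold (2.35 ± 0.15), from 7157 ± 228 to 36427 ± 4468 CPM for HERV3 (SD, n = 3). The edgeR adjusted p-values of these 3 features were 4.41e-20, 3.03e-14 and 1.79e-15. SST1 minus strand (0.90 ± 0.19) and ALR minus strand (1.19 ± 0.20) were also higher. Lower minus strands included those of the MaLR elements THE1C (-0.75 ± 0.12), MSTB1 (-0.87 ± 0.13) and MLT1E1 (-0.87 ± 0.24) and of L1PA12_3end, a 3′ end model of L1 (-0.80 ± 0.12; log2, SE).

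Calls numbered 21 higher and 18 lower of 70 at day 7, with 43 features at an unadjusted p under 0.05. The arms did not overlap for 39 features, 55.7% against the 10% of chance under the same condition. HERVL18, the internal part of an ERVL retrovirus, rose by 1.86 ± 0.49 on the plus strand, and the satellite CER rose 3.47-fold on the plus strand (1.797 ± 0.473), both at low levels (86.3 ± 37.4 and 119 ± 25 CPM in the non-targeting libraries, SD, n = 3). L1PBb_5end plus strand (1.27 ± 0.41), L1P1_orf2 plus strand (0.93 ± 0.14) and HERVK plus strand (0.84 ± 0.21) followed (log2, SE). The largest falls were in LTR26 minus strand (-1.30 ± 0.21), MER34C minus strand (-1.25 ± 0.35) and MLT2B5 minus strand (-1.01 ± 0.21). HUERS-P3b was lower on both strands (-0.84 ± 0.14 minus, -0.78 ± 0.15 plus), and LTR23-int was lower on the minus strand (-0.83 ± 0.21). L1P1_orf2 minus strand did not pass (-0.09 ± 0.13, edgeR adjusted p = 0.605). Unscaled counts gave 37 higher features and 1 lower, LTR26 minus strand (-0.69), so each other lower call rests on scaling to the table. L1PBb_5end was lost without SETDB1 sgRNA 9 day 7 replicate 2 (1.05).

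The satellite list was again higher at day 7, with 6 of its 7 features (both strands of SST1 and ALR, and CER and SATR1 plus strands) higher and 0 lower, and the same counts adjusted over the list alone; the libraries of the arms overlapped for ALR and SATR1 plus strands. Its camera adjusted p was 0.0315, but 0.109 as an adjusted p with an estimated correlation, which does not pass. At this day 6 of the 10 splits called at least as many lists, the real one included. Of the 10 MaLR features 5 were lower (both strands of MLT1E1, and THE1C, MSTB1 and MSTC minus strands) and 0 higher; the list did not pass camera (adjusted p = 0.14). The LTR list divided into 8 higher, such as LTR4 and HERV3, and 10 lower features of 27, with a median log2 change of 0.12 and a camera direction lower than the other features (median 0.19) that did not pass (adjusted p = 0.649). The LINE list divided into 7 higher and 7 lower of 35. The ERV1 list had 2 lower of 3 (LTR26 and LTR23-int), and the ERVL list 1 higher (HERVL18) and 1 lower (MLT2B5). These counts were the same when adjusted over the list alone, and the LINE, ERV1 and ERVL lists did not pass camera (adjusted p = 0.745, 0.248 and 0.909). The LINE and ERVL lists had medians of 0.08 and 0.12 and means of 0.10 and 0.33, with a camera direction lower than the other features (medians 0.26 and 0.17).

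**Figure D2:**
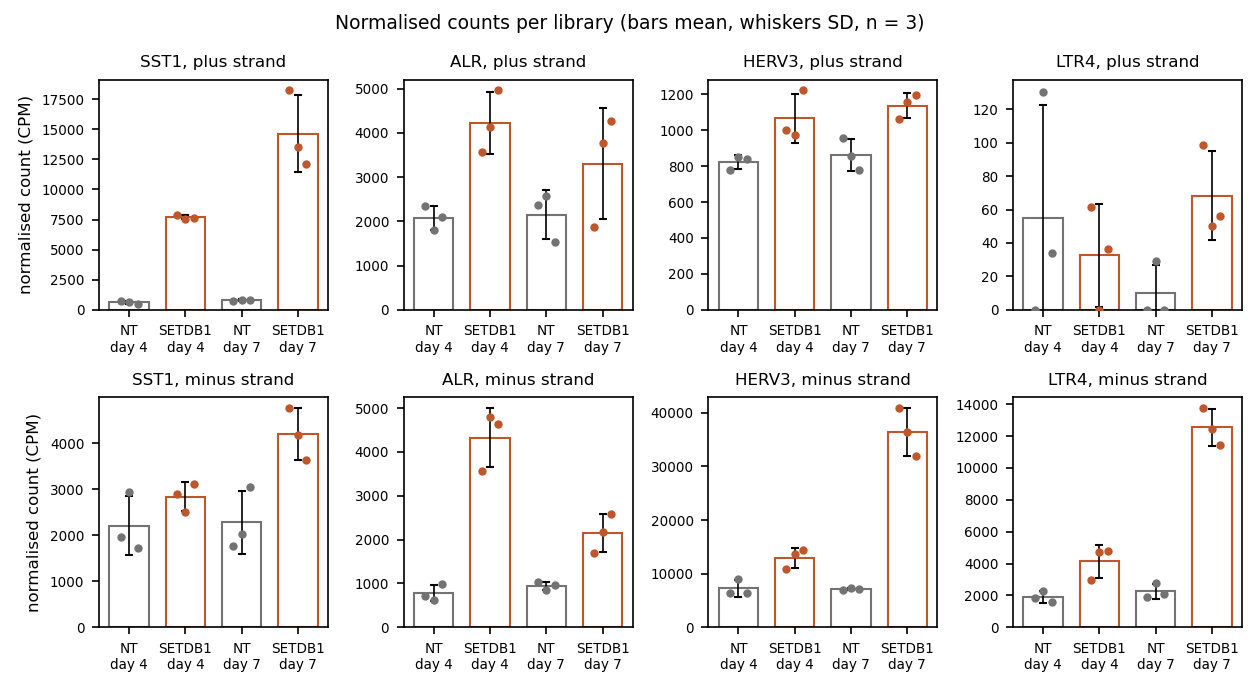
Normalised counts of SST1, ALR, HERV3 and LTR4 on the plus (top) and minus (bottom) strand in CPM of the table, with a point per library, bars at the mean and whiskers for the SD (n = 3; NT, non-targeting sgRNA). HERV3 minus strand rises from 7157 to 36427 CPM at day 7 and ALR minus strand is higher at day 4 (4329) than at day 7 (2152) in the SETDB1 libraries; LTR4 plus strand was too rare to be tested.

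The effect of SETDB1 sgRNA 9 grew between the days for HERV3 and LTR4. Their minus strands rose by a further 1.504 ± 0.208 and 1.35 ± 0.26 on the log2 scale (SE; edgeR interaction test, adjusted p = 1.76e-06 and 0.000387). ALR minus strand did the opposite: its rise was smaller at day 7 by a log2 difference of -1.30 ± 0.30 (adjusted p = 0.00326). For L1PA12_3end minus strand the difference was -0.63 ± 0.17 (adjusted p = 0.0125): it was higher at day 7 than at day 4 in the non-targeting cells (0.40 ± 0.12, adjusted p = 0.0422), and its change in the SETDB1 cells did not pass (-0.23 ± 0.12, edgeR adjusted p = 0.183). For SST1 plus strand the difference of 0.65 ± 0.30 did not pass (edgeR adjusted p = 0.16).

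These 4 features were the only calls of the interaction in 70, and 17 had an unadjusted p under 0.05. Across the 70 features the log2 changes of the days had a Pearson correlation of 0.777 and a Spearman correlation of 0.709; features are not independent replicates. Called at both days in the same direction were 9 higher features (3.3 for independent lists), among them SST1, LTR60 and L1PBa_5end plus strands, and 6 lower ones (1.54 for independent lists), among them both strands of HUERS-P3b. No feature was called in opposite directions. The split of 2 higher and 2 lower became 7 and 2 with table totals, 2 and 6 with DESeq2 size factors, 2 and 5 with L1P1_orf2 left out of the table after the data were seen and 2 and 1 without scaling. L1PA12_3end was lost without scaling and without any of 4 single libraries: SETDB1 sgRNA 9 day 7 replicate 2 or non-targeting day 4 replicate 3, day 7 replicate 1 or day 7 replicate 2.

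Few features differed between day 4 and day 7 in the non-targeting cells. MSTC minus strand (0.67 ± 0.15, adjusted p = 0.00867) and L1PA12_3end minus strand (0.40 ± 0.12, adjusted p = 0.0422) were higher at day 7, and HERV-Fc1 plus strand (-0.67 ± 0.20, adjusted p = 0.0422) and L1P1_orf2 plus strand (-0.52 ± 0.14, adjusted p = 0.0271) were lower (log2, SE; edgeR). These were 4 calls of 70 features, with 9 at an unadjusted p under 0.05. No call remained in unscaled counts or without replicate 3 of either non-targeting group, L1PA12_3end was lost without any of 9 of the 12 libraries and HERV-Fc1 and L1P1_orf2 each without any of 5, and the split of 2 higher and 2 lower became 5 and 0 with L1P1_orf2 left out, 2 and 1 with DESeq2 size factors and 1 and 2 with table totals.

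In the SETDB1 sgRNA 9 cells LTR4 minus strand was 3.02-fold and HERV3 minus strand 2.81-fold higher at day 7 than at day 4 (log2 1.60 ± 0.16 and 1.49 ± 0.14, SE). SST1 rose further on the plus strand (0.92 ± 0.14) and the minus strand (0.55 ± 0.17). HERVK, a beta-like endogenous retrovirus, rose on the minus strand (0.84 ± 0.15) and plus strand (0.57 ± 0.19), and HERVP71A minus strand by 0.74 ± 0.14. ALR minus strand fell to 2152 ± 438 from 4329 ± 676 CPM (SD, n = 3; log2 -0.99 ± 0.16). With L1MA8_3end minus strand (0.53 ± 0.13), named after its value was seen, these made 8 higher features and 1 lower of 70, with 20 at an unadjusted p under 0.05. DESeq2 size factors gave 6 higher and 5 lower, without HERVK plus strand and SST1 minus strand, whose calls were also lost without any of 7 and any of 4 of the 12 single libraries. Leaving out non-targeting day 4 replicate 2, which enters the shared fit but not the contrast, gave 7 higher and 17 lower features, of which 7 were among the 9.

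The share of an element's counts on the minus strand is a ratio within a library, so scaling between libraries does not enter it. Which strand is sense to the element is not given in the sources used here. SST1 turned from mostly minus to mostly plus: at day 4 the minus strand held 26.9% ± 2.1 of SST1 counts with SETDB1 sgRNA 9 and 77.1% ± 4.7 with the non-targeting sgRNA (SD, n = 3). At day 7 it held 22.5% ± 1.5 and 73.9% ± 4.4 (SD, n = 3; log2 odds change -3.20 ± 0.24 at day 4 and -3.30 ± 0.23 at day 7, SE). ALR moved the other way at day 4, from 27.0% ± 4.3 to 50.6% ± 2.8 (1.47 ± 0.26), and HERV3 at day 7, from 89.2% ± 1.2 to 96.9% ± 0.5 (1.94 ± 0.23). THE1C and MSTB1 lost minus strand share at both days: at day 7 THE1C went from 62.1% ± 2.5 to 44.8% ± 0.4 and MSTB1 from 60.1% ± 1.9 to 42.4% ± 2.9 (SD, n = 3).

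At day 4 the minus strand share was higher for 1 of 39 elements (ALR) and lower for 4: SST1, L1PBa_5end (-0.77 ± 0.19), MSTB1 (-0.58 ± 0.17) and THE1C (-0.43 ± 0.15, edgeR adjusted p = 0.0449). At day 7 it was higher for 3, HERV3, L1MA8_3end (0.59 ± 0.17) and L1PBa1_5end (0.62 ± 0.24), and lower for 10. Besides SST1, THE1C (-1.01 ± 0.15) and MSTB1 (-1.03 ± 0.17), these were LTR23-int (-1.39 ± 0.43), MLT2B5 (-1.11 ± 0.38), L1P1_orf2 (-1.001 ± 0.189), L1PBa_5end (-0.63 ± 0.19), L1MA5_3end (-0.53 ± 0.16), L1PA10_3end (-0.40 ± 0.15) and L1PA12_3end (-0.38 ± 0.15; log2 odds, SE). The median change over all 39 elements was itself -0.25 at day 4 and -0.42 at day 7, and the minus strand share of all table counts went from 70.5% ± 2.2 to 71.0% ± 4.3 at day 4 and from 74.6% ± 0.7 to 69.9% ± 1.4 at day 7 (SD, n = 3). In a comparison chosen after the values were seen, THE1C and MSTB1 at day 4 and L1MA5_3end, L1PA10_3end, L1PA12_3end, L1PBa_5end and MLT2B5 at day 7 lay no more than 2 SE below the median element. L1P1_orf2 had the most counts behind it, 54480 and 34009 in the arms, and its minus strand share went from 87.9% ± 0.4 to 78.3% ± 2.4 at day 7 (SD, n = 3). At an unadjusted p under 0.05 there were 8 elements at day 4 and 18 at day 7. HERV-Fc1 had 0 of 854 counts on the minus strand over the 12 libraries, which allows a share of up to 0.351%. The day 4 falls of THE1C and MSTB1 did not pass with limma on the log2 ratio, nor without SETDB1 sgRNA 9 day 4 replicate 3 or non-targeting day 4 replicate 1, and the day 4 call of THE1C was lost without any of 8 of the 12 libraries. The day 7 calls of L1PA10_3end, L1PA12_3end, LTR23-int and MLT2B5 did not pass with limma at a pseudocount of 0.5, and single libraries whose removal ended a day 7 call numbered 8 of 12 for L1PA12_3end, 5 for L1PA10_3end, 5 for L1PBa1_5end (all day 7 libraries but SETDB1 sgRNA 9 replicate 2), 2 each for LTR23-int and MLT2B5 and 1 for L1PBa_5end (non-targeting day 7 replicate 2).

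**Figure D3:**
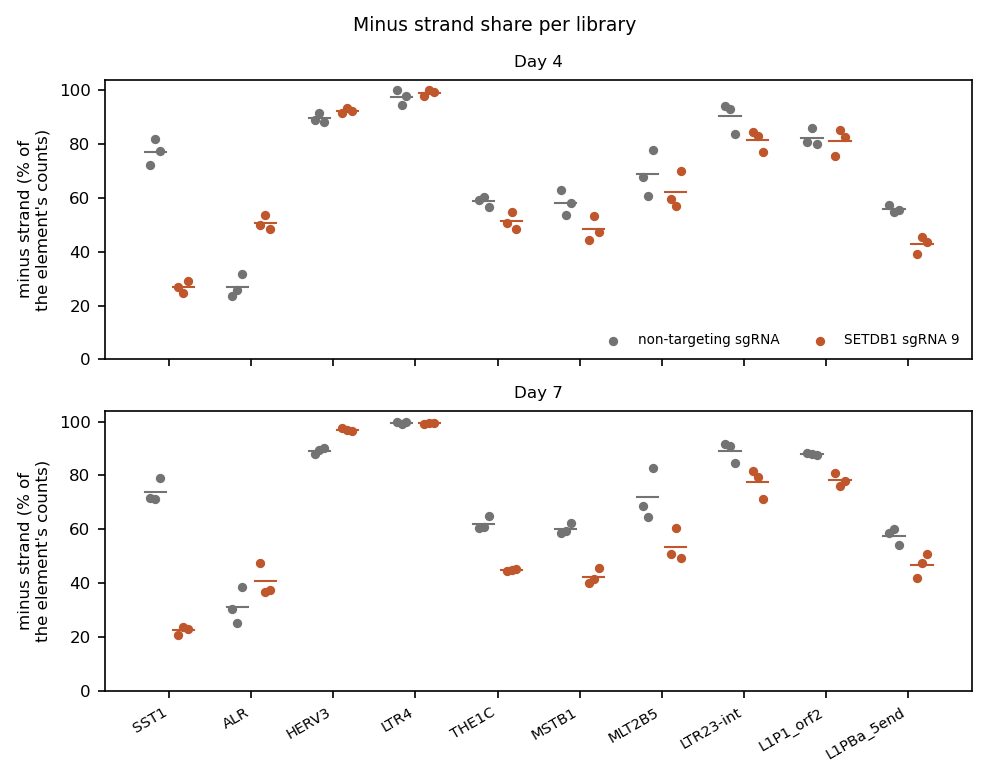
Percent of each element's counts on the minus strand in every library at day 4 (top) and day 7 (bottom), with grey points for the non-targeting sgRNA, orange points for SETDB1 sgRNA 9 and a line at each mean (n = 3). SST1 falls from 77.1% to 26.9% at day 4 and from 73.9% to 22.5% at day 7, while ALR rises from 27.0% to 50.6% at day 4.

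The series asks about both strands of an element, and elements higher on both were counted. Counts are per element without genomic positions, and what the plus and minus columns refer to is not given. A rise on both therefore need not mean that the same copy was transcribed in both directions. ALR was the 1 element higher on both strands at day 4, of 31 with both strands tested. ALR, HERVK and SST1 were higher on both strands at day 7, though the libraries of the arms overlapped for ALR plus strand (0.62 ± 0.21; log2, SE). HERVK rose by 0.84 ± 0.21 on the plus and 0.37 ± 0.15 on the minus strand (log2, SE). Independent lists would share 0.645 elements at day 4 and 2.06 at day 7, from 4 plus and 5 minus strand calls and from 8 and 8 (one-sided Fisher's exact p = 0.525 and 0.331, neither past the threshold). The number rose to 11 and 10 in unscaled counts, and at day 7 it was 6 with table totals and 1 with the DESeq2 Wald test, with no count filter and with each day fitted alone. It was 1 at day 7 without SETDB1 sgRNA 9 replicate 2 or non-targeting replicate 3 of that day, and 2 at day 4 without non-targeting day 4 replicate 2.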

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

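Chosen only after the results were seen were the tests of library scaling, of genomic DNA, of a strand shift shared by the whole table and of a single divergent library; the last reads a planned refit. Flagged here is the difference of the SETDB1 sgRNA 9 effect between day 7 and day 4, which the interaction test called for 4 features: HERV3 minus strand (1.504 on the log2 scale), LTR4 minus strand (1.35), ALR minus strand (-1.30) and L1PA12_3end minus strand (-0.63). Of 100 splits of the days within each arm, 9 called at least 4 features, the real one included, and the highest other called 8. The arms were split separately, so a split could keep the real days of the SETDB1 cells and mix only those of the non-targeting cells. Such a split retains the change with time in the SETDB1 cells, which had 9 calls. This share therefore cannot decide the question, and chance is not excluded for this count.

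For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. At day 4 the real split called 17 features and the highest other 2; at day 7 the values were 39 and 0. For day 7 against day 4 they were 4 and 0 in the non-targeting and 9 and 0 in the SETDB1 cells. For the minus strand share they were 5 and 5 at day 4, where 2 of the 10 splits gave as many, and 13 and 0 at day 7. For elements higher on both strands they were 1 and 0 at day 4 and 3 and 0 at day 7. For lists they were 1 and 2 at day 4, where 4 of the 10 splits gave as many, and 1 and 1 at day 7, where 6 did. In the other comparisons 1 split, the real one, gave as many.

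The first pattern weighed is the rise of SST1 plus strand, HERV3 minus strand and LTR4 minus strand. Library scaling moves every feature of a library alike, so it cannot by itself give a rise over the other elements. The smallest excess of these 3 features over the median feature was 0.80 ± 0.15 on the log2 scale (SE, HERV3 at day 4). They were picked for their rise, so this excess restates their calls and adds no further support. Genomic DNA in the SETDB1 libraries would add counts to both strands, yet the gain of these elements was 8.20% to 12.2% on the minus strand for SST1 and 96.0% to 101% for HERV3 and LTR4 (LTR4 plus strand was slightly lower at day 4); the value nearest to 50% was 12.2%, and no pair of libraries came between 40% and 60%. These features were picked for a rise on a named strand, which favours a lopsided gain. The values therefore concern these features only and do not exclude genomic DNA elsewhere in the libraries. How reads shared between copies were counted stays open and was not tested. The rise may be an effect of SETDB1 loss, as a hypothesis found and examined on the same libraries, with a single SETDB1 sgRNA named in the titles and no measure of SETDB1 itself.

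The second pattern is the features called lower with SETDB1 sgRNA 9. Only 1 of the 18 lower at day 7, LTR26 minus strand, was also called lower in unscaled counts, where 12 of the 18 had negative values; library depth is not known, so a fall in these elements and a rise in the others cannot be told apart. For THE1C and MSTB1 part of the pattern escapes this: their minus strands fell against their own plus strands within libraries, with a log2 odds change nearest to 0 of -0.43 ± 0.15 (SE; THE1C at day 4, over both elements and days), which no factor per library can give. A strand shift shared by the whole table is a further explanation, as the median element also lost minus strand share. The minus strand share of all table counts was lower with SETDB1 sgRNA 9 at day 7 (69.9% ± 1.4 against 74.6% ± 0.7, SD, n = 3). At day 4 it was not lower (71.0% ± 4.3 against 70.5% ± 2.2, SD, n = 3). At day 7 THE1C and MSTB1 fell further than the median element, the excess nearest to 0 being -0.588 ± 0.151 (log2 odds, SE, THE1C). Both elements were chosen for their fall, and this SE leaves out the error of the median. The day 7 excess therefore does not exclude a shared shift. At day 4 the excess was -0.18 ± 0.15 (log2 odds, SE, THE1C), so there the shared shift and a fall of their own cannot be told apart with this spread.

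The third pattern is ALR, which rose on both strands, with a smaller minus strand rise at day 7. The smaller rise does not come from SETDB1 sgRNA 9 day 7 replicate 1 alone, since without it the difference was still -1.15 ± 0.30 (log2, SE; edgeR adjusted p = 0.00769). The minus strand took 62.3% of the ALR gain at day 4 and 51.1% at day 7, with pairs of libraries between 55.9% and 69.6% at day 4 and between 35.2% and 523% at day 7 (over 100% where the plus strand was lower). Genomic DNA, which would give values near 50%, and RNA from both strands cannot be told apart by these values, as the day 7 gain is too small to fix its share. A loss of SETDB1 that acts on centromeric repeats may be a further explanation and was not tested separately.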

How the results depend on the processing

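Library depth is unknown, and the median feature moved by 0.62 (day 4) and 0.60 (day 7) on the log2 scale without scaling, by -0.10 at day 4 and 0.20 in the interaction with table totals, and by -0.10 in the interaction with DESeq2 size factors. Without scaling 35 features were called at day 4, 11 (day 4) and 10 (day 7) elements were higher on both strands, and the non-targeting cells had 0 calls between the days. The minus strands of HUERS-P3b (0.026), MSTB1 (0.14), THE1C (0.17), LTR23-int (0.093) and MLT2B5 (0.31) then turned positive at day 4, and so did L1P1_orf2 (0.51) at day 7. The interaction, with 4 calls, gave 8 with DESeq2 size factors and without a filter, 9 with table totals, 7 with a mean count of at least 50, limma-voom or L1P1_orf2 left out (chosen after seeing the data) and 10 with the DESeq2 Wald test; the 4 features were among the calls each time. Elements higher on both strands were 2 at day 4 with DESeq2 size factors or the Wald test, and at day 7 were 6 with table totals and 1 without a filter, with the Wald test or with each day fitted alone. Day 4 alone gave 10 calls. The day 4 strand share gave 3 calls with limma (pseudocount 0.5). Day 7 lists called were 0 with an estimated correlation and 3 with fry (satellites up, MaLR and the ERV1 list down, the latter only LTR23-int and LTR26, without HERV3 and LTR4). The causes were not tested, other than that the strict filter and the day 4 fit tested fewer features or samples and that fry tests against no change. Leaving out 1 library at a time gave 10 (without SETDB1 day 4 replicate 3) to 18 calls at day 4, 28 to 41 at day 7, 3 to 9 (without SETDB1 day 4 replicate 1) in the interaction, 0 (without non-targeting day 4 or day 7 replicate 3) to 4 in the non-targeting and 7 to 24 (without non-targeting day 4 replicate 2) in the SETDB1 time comparison, 3 (without SETDB1 day 4 replicate 3 or non-targeting day 4 replicate 1) to 7 and 9 to 14 for the strand share at the days, 1 to 2 and 1 to 4 elements on both strands, 1 and 1 to 2 (without SETDB1 day 7 replicate 1) lists, and -0.21 to 0.0030 (without non-targeting day 7 replicate 1) for L1P1_orf2 minus strand at day 7. Replicate numbers did not pair the samples (same-number correlations -0.311 to 0.279); with a replicate block the calls were 18 at day 4, 41 at day 7, 5 in the interaction, 3 and 9 for time in the non-targeting and SETDB1 arms, and 5 and 11 for the strand share. Of the results of single named features, 518 kept their side of the threshold, 51 lost it, 9 gained it and 6 reversed under the alternatives other than leaving out a library, and 768, 79, 4 and 1 did so when a library was left out. Library totals with rows naming no feature were not run, as the tables used hold no such rows. Depth limits the rarest features: the 20 not tested had mean counts up to 7.58.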

Other observations

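Chosen only after the values were seen were the 10 ratios and shares compared within libraries here, each by a two-sided exact permutation over the 400 relabellings of the arms within days (smallest p = 0.005). The summed counts of LINE L1 models of the 5′ end (13 models) gained on those of the 3′ end (5 models) within libraries. The 5′ counts were 0.373 ± 0.036 of the 3′ counts with SETDB1 sgRNA 9 and 0.269 ± 0.076 with the non-targeting sgRNA at day 4, and 0.389 ± 0.036 and 0.215 ± 0.017 at day 7 (SD, n = 3; exact p = 0.01, adjusted 0.0143). The same held on each strand (exact p = 0.01 for both) and without L1P1_5end, the largest 5′ model (exact p = 0.005). The ratio was not run without L1PA5_3end, the largest 3′ model. A ratio of sums also moves with the mix of models. The libraries of the arms overlapped at day 4 for the ratio over all 5′ models. The models did not all move this way in the planned edgeR calls at day 7. Of the 12 5′ models with a tested strand, 5 had a strand called higher and 1 had a strand called lower (L1M4b_5end minus strand, log2 -0.56). Of the 5 3′ models, 4 had a strand called lower and 1 had a strand called higher (L1MA8_3end minus strand, 0.46). L1P1_orf2 also gained on the 3′ models, at 1.15 ± 0.10 against 0.841 ± 0.121 at day 4 and 1.14 ± 0.02 against 0.751 ± 0.042 at day 7 (SD, n = 3; exact p = 0.005). A hypothesis is that SETDB1 loss raises RNA that starts at L1 5′ ends over 3′ fragments read from other transcripts. It may be followed up by position. The ratio was chosen after the values of these libraries were seen, so its exact permutation p = 0.01 is no independent support for it. The source of the difference was not tested.

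The MaLR elements THE1C, MLT1E1, MSTB1, MSTC and MSTB2, summed, had a lower minus strand share with SETDB1 sgRNA 9, but THE1C and MSTB1, whose shares had drawn attention to the group, hold 81.7% to 83.9% of these counts. MLT1E1, MSTC and MSTB2 summed without them had a minus strand share of 53.1% ± 3.0 with SETDB1 sgRNA 9 and 58.6% ± 1.2 with the non-targeting sgRNA at day 4, and 59.9% ± 2.0 and 65.8% ± 0.6 at day 7 (SD, n = 3; exact p = 0.005). A summed share also moves with the mix of elements, and with equal weight for each of the 3 the mean share was 45.2% ± 1.4 and 50.3% ± 1.5 at day 4, and 48.2% ± 1.2 and 50.3% ± 1.8 at day 7, where the libraries of the arms overlapped (SD, n = 3; exact p = 0.015). In the planned edgeR test none of the 3 was called alone at either day, and MSTB2 hardly moved at day 4 (log2 odds change -0.092 ± 0.262, SE) and was higher, not lower, at day 7 (27.6% ± 2.2 against 25.3% ± 4.4; SD, n = 3; edgeR adjusted p = 0.677). The fall of the 3 (larger exact p = 0.015) was not told from a strand shift shared by the whole table: the log2 odds of their summed minus strand counts, less those of all elements outside MaLR, were -1.23 ± 0.38 against -0.841 ± 0.111 at day 4 and -0.769 ± 0.008 against -0.709 ± 0.104 at day 7 (SETDB1 sgRNA 9 against non-targeting; SD, n = 3; exact p = 0.115). A shift of MaLR elements beyond THE1C and MSTB1 is therefore not shown.

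HERV3 and its long terminal repeat LTR4 rose by similar amounts on the minus strand. LTR4 counts were 0.316 ± 0.037 of HERV3 counts with SETDB1 sgRNA 9 and 0.264 ± 0.022 without it at day 4, and 0.346 ± 0.011 and 0.314 ± 0.057 at day 7 (SD, n = 3). A difference of this ratio between the arms was not detected (exact p = 0.065), which leaves a small one open.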
